A study of Mus musculus with 32 samples.

How the data were processed

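RNA was sequenced from cells sorted by flow cytometry from mouse brain. Per the labels, 32 libraries came from 4 populations of 8 libraries each. Tumour microglia, tumour differentiated macrophages and tumour undifferentiated macrophages came from chimeric mice carrying intracranial GL-261 tumours, a mouse glioma line that grows in immunocompetent mice of the matching strain. Normal microglia came from mice without a tumour. In each population 4 libraries came from C57BL/6J recipients, called WT here, and 4 from recipients of the strain labelled Pep3/CD45.1. The tumour populations were labelled as Pep3 into WT or WT into Pep3. Normal microglia were labelled Nil with a strain and no graft, so for them recipient means only the strain of the mouse. The sorting gates were not given in the sources used here. Per the labels' protocols, cDNA was made with a low-input SMART-Seq v4 kit from Clontech. The labels do not say that libraries came from separate animals, so p-values measure the spread between these libraries, part of which may be technical.

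Reads were processed with FastQC, STAR 2.5.0a and RSEM 1.3.0 on genome build mm9, per the submitters' processing notes. The authors' table held 17586 genes in 32 libraries, and its name calls the values normalised counts. The deposited values were treated as scores of unstated scale, because they ran from -6.50 to 6.92. Every gene had a mean of 0 over all libraries and also within each recipient strain. The 32 libraries spanned 21 dimensions, so 11 sample directions carried no variation: the overall mean, the recipient strain difference and 9 more that the labels do not name. Which step removed them was not given in the sources used here. The SD of a gene ranged from 0.206 to 2.78 with a median of 0.890, which is a log-like spread, but the base of a logarithm was not stated. Differences are therefore given in units of the deposited scale, with no fold changes and no expression levels. Sequencing depth is unknown, and the precision of low-level genes could not be assessed from it.

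The removed directions took unequal shares from the libraries. The share of its own variation that a library kept was the squared length of its axis left after removing the 11 directions. It was under 50% in 9 libraries, with 38.96% the highest among these and 66.02% the lowest among the other libraries. Summed over a population, 4.04 of 8 library equivalents were kept in normal microglia, 6.32 in tumour microglia, 5.32 in differentiated and 5.31 in undifferentiated macrophages. No library was a copy of another, and the highest correlation between 2 libraries was 0.889.

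Differences were tested with limma 3.58.1 in R 4.3.3, on all 17586 genes and all 32 libraries, with robust empirical Bayes variances, two-sided p-values and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. With no differences, about 5% of the 17586 genes would have an unadjusted p below 0.05, so a smaller count shows no excess. The model held a mean for each population and recipient strain, and the 11 removed directions as covariates, which left 15 residual degrees of freedom. Contrasts were averaged over the recipient strains. The planned model had been a limma trend fit on log2 values after a filter on low values. Signed scores have no such logarithm and no level to filter on, so the values were used as deposited, with no filter, pseudocount or trend. The removed directions were entered as covariates after the structure of the table was seen. The percent of each contrast left after removing the directions was 96.7 for tumour against normal microglia, 91.9 for differentiated macrophages against tumour microglia, 85.4 for undifferentiated macrophages against tumour microglia and 67.6 for differentiated against undifferentiated macrophages. A contrast between recipient strains within 1 population could not be estimated, since the removed recipient direction takes it up. Only the difference between recipient strains in a population contrast could be tested.

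The model was tested on simulated data with the real residual SDs and removed directions, independent noise, 17586 genes and 200 changed genes. Of unchanged genes, 5.12% had an unadjusted p below 0.05 for tumour against normal microglia, 4.97% for differentiated macrophages against tumour microglia, 4.94% for undifferentiated macrophages against tumour microglia and 5.25% for differentiated against undifferentiated macrophages. Without the covariates these shares were 9.69, 8.68, 7.79 and 4.53%. With the leading residual directions of the simulated table removed in place of the real ones, the shares with covariates were 5.24, 5.13, 5.02 and 5.33%. With the real directions removed, genes changed by 1 unit were recovered in 4, 4, 2 and 2% of cases in that order of comparisons. At 2 units recovery was 78, 72, 58 and 40%, at 3 units 98, 96, 96 and 98%, and at 4 units 100, 100, 96 and 94%. With the leading residual directions removed recovery was 10, 6, 10 and 10% at 1 unit and 72, 64, 76 and 82% at 2 units. With independent noise and the real directions entered in the fit, a share near 5% follows from the setting. The leading residual directions were taken after population, so unlike the real ones they removed nothing of the contrasts. Neither simulation tests how the unnamed directions arose in the real data.

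Gene lists for myeloid cell states, immune and metabolic pathways, and markers of other cell types were fixed before the data were examined, as were the comparisons, the rule for named genes and a first set of other settings. Lists of at least 3 measured genes, 32 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Beside it stood camera with an estimated correlation and limma's fry. Camera compares a list with the other genes, so a list can be called lower while its own median difference is above 0. Names were matched to symbols: 13971 of the 17586 genes carried a current GENCODE symbol and 15755 a symbol or known synonym. Markers without a match were not analysed here. Coordinates are not given, because the reference annotation belonged to another genome build.

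Named genes were the 6 largest and 6 smallest differences among called genes whose 8 and 8 deposited values did not overlap, leaving out predicted genes and antigen receptor segments, a fixed set of marker genes, and up to 3 called members of each list with the largest differences. The parts of the rule that needed a mean level, a minimum of 100 and the highest member that did not pass, could not be applied to values without levels. Fewer genes are printed than the rule allows, and some that it names are not reported here. Genes with near-identical copies, among them C4a and C4b, H2-K1 and H2-D1, Ly6c2, Oas1a, Klra2 and Lilrb4, are uncertain, since reads shared between copies may be split between them.

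Alternatives were population means without recipient strain, a term for sets of 8 consecutive library numbers, limma library weights, a minimum difference of 1 unit, quantile normalisation, WT or Pep3 recipients alone with the covariates kept, only the libraries of the groups compared, and each library left out in turn. Others were added after the data were seen: no term for the removed directions, the median of each library subtracted, and leaving out the 9 libraries that kept under 50% of their own variation, with and without the covariates. Library numbers ran from 1 to 32 without repeats. Each run of 8 consecutive numbers held 1 library of every population and recipient strain, but the labels do not say that these share an animal or a day, so a term for these sets was fitted as an alternative. Normal microglia came from experiments 1 and 2, with 1 recipient strain in each, and the tumour populations from experiments 3 and 4, so experiment and tumour cannot be told apart. Only the tumour populations were labelled with a graft, so grafting and tumour cannot be told apart either. Each of experiments 3 and 4 held 4 libraries of every tumour population, of 1 recipient strain each. Microglia and macrophages of 1 experiment came from opposite recipient strains, and the recipient difference had been removed, so their contrast could not be estimated within an experiment. Differentiated and undifferentiated macrophages of 1 experiment shared a strain, so WT or Pep3 recipients alone gave their contrast within experiment 3 or 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.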

Results

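The data were gene expression scores of 32 libraries of cells sorted from mouse brain: 8 of normal microglia, 8 of tumour microglia, 8 of tumour differentiated macrophages and 8 of tumour undifferentiated macrophages. Microglia are the resident macrophages of the brain parenchyma, and the tumour macrophages are the sorted cells that the labels set apart from them. Each population held 4 libraries from WT and 4 from Pep3 mice, and only the tumour populations were labelled with a graft. Sequencing depth is unknown. Differences are in units of the deposited scale and are given with ± 1 standard error, for 8 libraries against 8.

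Population was the main axis of variation in the deposited values, from which 11 directions had already been removed. The first principal component held 36.5% of the variance, of which population explained 82.8%, and the second held 11.03%, of which population explained 73.5%. Library medians ran from -0.628 to 0.581. They averaged -0.331 ± 0.197 (SD, n = 8) in tumour microglia and -0.142 ± 0.185 in normal microglia, against 0.290 ± 0.172 in differentiated and 0.289 ± 0.116 in undifferentiated macrophages. Under 50% of its own variation was left in normal microglia libraries 10, 18, 26 and 1, tumour microglia library 27, differentiated macrophage libraries 28 and 31, and undifferentiated macrophage libraries 29 and 8. The lowest shares were 3.42% in undifferentiated macrophage library 29 and 8.60% in normal microglia library 10.

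**Figure D1:**
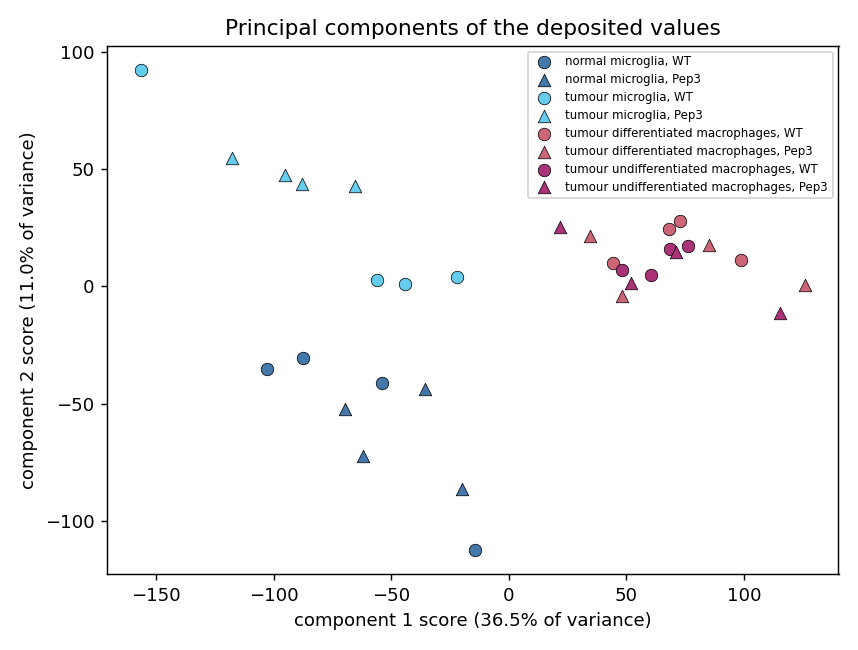
Scores of the 32 libraries on the first principal component (36.5% of the variance, x axis) and the second (11.03%, y axis), with 1 point per library, colours for the 4 populations, circles for WT and triangles for Pep3 recipients. Population explained 82.8% of the first component and 73.5% of the second.

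**Figure D2:**
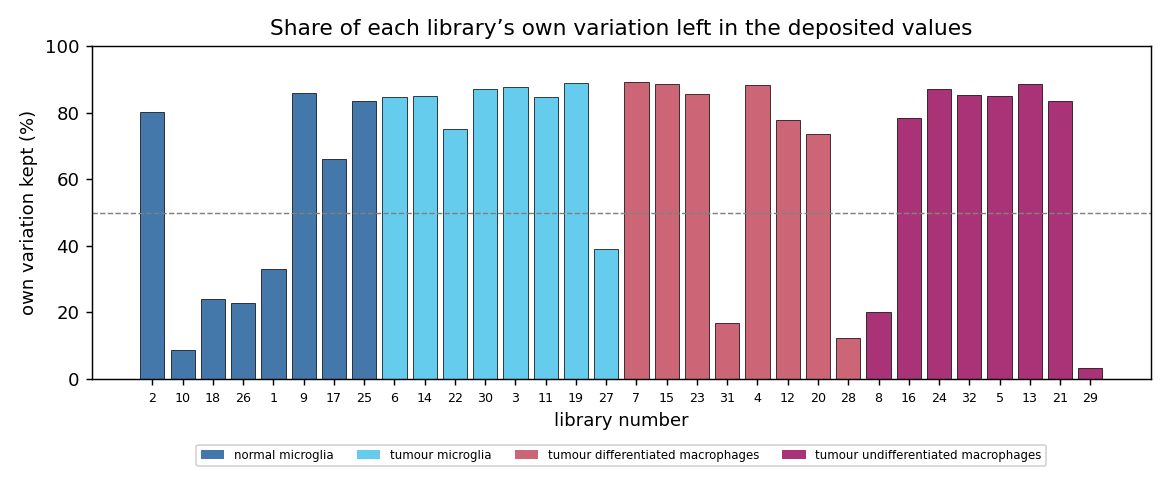
Percent of its own variation that each of the 32 libraries kept after the directions without variation were taken out, as 1 bar per library grouped by population, with a dashed line at 50%. The 9 libraries under the line kept 38.96% or less, and all other libraries kept 66.02% or more.

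Tumour against normal microglia compared microglia of grafted, tumour-bearing mice with those of mice without a tumour or a labelled graft. Interferon-response, antigen-presentation, chemokine and cell-cycle genes were higher in tumour microglia, and 2 of 16 homeostatic microglia genes were lower. Oas2 and Oas1a, antiviral 2'-5' oligoadenylate synthetases, rose by 3.66 ± 0.35 and 3.54 ± 0.48, the ubiquitin-like interferon product Isg15 rose by 3.36 ± 0.42, and Ifit3, an interferon-induced RNA-binding family member, rose by 3.13 ± 0.47. For each of these 4 genes the 8 tumour and 8 normal libraries did not overlap, and the highest adjusted p among them was 0.00028. Lack of overlap was a condition for genes named by the size of their difference, so for those it is no support. Some of the normal libraries kept little of their own variation, so their values are not independent. Of the 15 measured type I interferon response genes, 13 rose, 0 fell and 2 did not pass, and 14 rose when adjusted over the list alone (camera adjusted p = 1.9e-19).

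Antigen presentation genes rose in both classes. H2-K1 and H2-D1, the classical MHC class I heavy chains of this strain background, rose by 2.40 ± 0.27 and 2.11 ± 0.27, and Nlrc5, a transactivator of class I genes, rose by 2.35 ± 0.38. Of 12 class I genes, 8 rose, 0 fell and 4 did not pass, and 9 rose when adjusted over the list alone (camera adjusted p = 4.4e-12). Among class II genes, the invariant chain Cd74 rose by 3.45 ± 0.38, and the chains H2-Ab1 and H2-Eb1 rose by 3.22 ± 0.38 and 2.99 ± 0.37. The score of H2-Ab1 was -3.21 ± 0.67 (SD, n = 8) in normal and 0.06 ± 0.94 (SD, n = 8) in tumour microglia. Of 11 class II genes, 6 rose, 0 fell and 5 did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 2.4e-10). In Pep3 recipients the deposited scores of H2-Ab1 were -0.17 ± 1.27 (SD, n = 4) in tumour and -2.92 ± 0.83 (SD, n = 4) in normal microglia, and the means differed by 2.76, with 2.78 for Cd74 and 2.40 for H2-Eb1. The 4 and 4 Pep3 libraries did not overlap for these 3 genes. Normal microglia libraries 10, 18 and 26 among them kept only 8.60, 23.9 and 22.8% of their own variation. Their values are therefore not independent, and the SD and the lack of overlap are weak evidence. A fit to the Pep3 recipients alone, with terms for the removed directions and 3 residual degrees of freedom, gave Cd74, H2-Ab1 and H2-Eb1 differences of the opposite sign, -0.33, -0.60 and -1.25, none of which passed. The difference between the strains did not pass for these 3 genes, with adjusted p of 0.19, 0.28 and 0.084.

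Secreted factors followed. Ccl2, which attracts monocytes, rose by 3.20 ± 0.43, and Cxcl10, an interferon-induced attractant of T cells, rose by 3.18 ± 0.42. Of 13 chemokines, 9 rose, 0 fell and 4 did not pass, and 11 rose when adjusted over the list alone (camera adjusted p = 5.7e-11). Tnf, an inflammatory cytokine, rose by 2.88 ± 0.50, in a list of 11 cytokines of which 4 rose, 0 fell and 7 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 6.5e-05). C4a, whose near-identical neighbour is C4b, rose by 4.12 ± 0.37, and Cd300lf, an inhibitory myeloid receptor, rose by 3.66 ± 0.33. Of 11 complement genes, 4 rose, 0 fell and 7 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 1.3e-05). Tnf was not called without normal microglia library 1 (2.97), and its fitted difference in Pep3 recipients alone was -0.16, where the deposited means differed by 2.18.

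Cell-cycle and metabolic lists were also higher. Of 19 proliferation genes, 10 rose, 0 fell and 9 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 2.4e-10). Top2a, a topoisomerase of dividing cells, rose by 2.24 ± 0.51, but was not called without normal microglia library 10 (1.60). Of 16 oxidative phosphorylation genes, 4 rose, 0 fell and 12 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 7.8e-05). Of 15 glycolysis genes, 4 rose, 0 fell and 11 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 0.0038, but adjusted p = 0.23 with an estimated correlation). Of 16 immediate early genes, which tissue dissociation can also induce, 6 rose, 0 fell and 10 did not pass, and 8 rose when adjusted over the list alone. Their camera adjusted p was 3.3e-06, and adjusted p = 0.12 with an estimated correlation.

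Of 17 genes of the disease-associated microglia list, 4 rose, 1 fell and 12 did not pass, and 7 rose and 1 fell when adjusted over the list alone. Its camera adjusted p was 8.3e-05, and adjusted p = 0.052 with an estimated correlation. Among its members, the phagocytic receptor tyrosine kinase Axl rose by 2.78 ± 0.48 and Cst7, a cystatin protease inhibitor, by 2.71 ± 0.40. Axl was not called without normal microglia library 10 (1.92) or 1 (2.31), nor Cst7 without normal microglia library 1 (1.81), and Cst7 had a fitted difference of -0.69 in Pep3 recipients alone, where the deposited means differed by 2.01. Of 14 immune checkpoint genes, 2 rose, 2 fell and 10 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.12). In that list the inhibitory receptor Lilrb4 rose by 2.70 ± 0.35.

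Of 16 homeostatic microglia genes, 2 fell, 0 rose and 14 did not pass, and 3 fell when adjusted over the list alone. The camera adjusted p was 0.023, and adjusted p = 0.42 with an estimated correlation. Tmem119, a microglial surface marker, fell by 1.08 ± 0.29 (adjusted p = 0.014), and with the median of each library subtracted its difference was -0.83 (adjusted p = 0.053). Its call was also lost without normal microglia library 10 (-0.60), 18 (-0.93) or 1 (-1.10), or tumour microglia library 27 (-0.96). P2ry12, a purinergic receptor of microglia, had a difference of -0.53 ± 0.40 (adjusted p = 0.38), the transcription factor Sall1 -0.56 ± 0.39 (0.34), and the fractalkine receptor Cx3cr1 -0.81 ± 0.28 (0.051). Cx3cr1 was called lower without normal microglia library 17 (-0.83), differentiated macrophage library 31 (-0.81) or 28 (-0.86), or undifferentiated macrophage library 29 (-0.81). Arg1, an arginine-degrading enzyme, had a difference of 1.62 ± 0.83 (adjusted p = 0.19).

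Markers of other cell types moved beside these lists. Of 5 T cell markers, 4 fell, 0 rose and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.23 with an estimated correlation). Of 7 glioma cell markers, 4 fell, 0 rose and 3 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.25 with an estimated correlation). Of 6 neuron markers, 2 fell, 0 rose and 4 did not pass, and 3 fell when adjusted over the list alone (camera adjusted p = 0.033, but adjusted p = 0.086 with an estimated correlation). Of 7 dendritic cell markers, 2 rose, 0 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.046, but adjusted p = 0.18 with an estimated correlation). Of 12 lipid efflux genes, 3 rose, 1 fell and 8 did not pass, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.014, but adjusted p = 0.14 with an estimated correlation).

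In all, 820 genes were higher and 2116 lower in tumour microglia. The median difference of all genes was -0.245, and with the median of each library subtracted 1358 genes were higher and 1336 lower, among them 820 and 1336 of the genes above. By camera, 13 of the 32 lists were higher and 4 lower, and with an estimated correlation 8 were higher and 0 lower: interferon response, both MHC classes, chemokines, inflammatory cytokines, complement, proliferation and oxidative phosphorylation. With the medians subtracted, 14 interferon, 10 class I, 7 class II, 10 chemokine, 5 cytokine, 6 complement, 11 proliferation, 5 oxidative phosphorylation, 6 glycolysis, 8 immediate early, 2 dendritic cell and 5 lipid efflux genes rose, and 0 of these lists' genes fell. In the same setting 7 disease-associated microglia genes rose and 0 fell, 5 immune checkpoint genes rose and 1 fell, and 1 homeostatic, 3 T cell, 4 glioma and 1 neuron gene fell. The list median and the test differed in sign for monocyte-derived macrophage, immune checkpoint and oligodendrocyte genes, none of which was called. The counts fell to 89 higher and 82 lower without normal microglia library 1, 267 and 519 without 10, 326 and 349 without 18, 357 and 1128 without 26, and 318 and 424 without tumour microglia library 27. Without all 9 libraries that kept under 50%, limma called 0 genes with the terms for the removed directions (6 residual degrees of freedom, 1866 at an unadjusted p under 0.05), and without these terms 109 higher and 24 lower, 94 and 20 of them among the genes above. Fitted to only the libraries of the groups compared (3 residual degrees of freedom), limma called 214 higher and 259 lower, 206 and 255 of them among the genes above, and with library weights 208 and 537, of which 204 and 532 were among them. It called 0 in WT (1959) or Pep3 recipients alone (1895). The normal and tumour libraries came from different experiments, and only the tumour libraries were labelled with a graft. Neither experiment nor grafting can be told apart from tumour here.

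**Figure D3:**
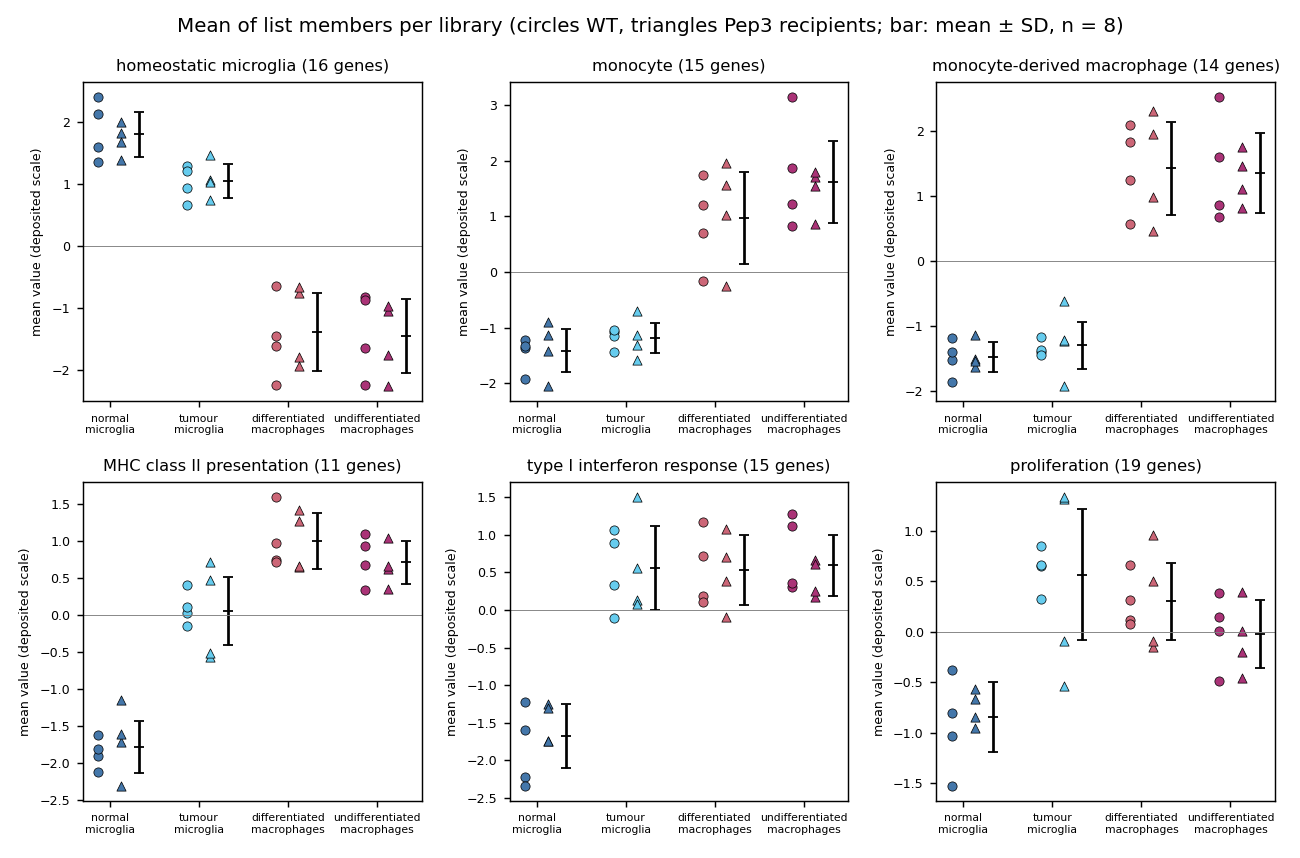
Mean score of the members of 6 gene lists in each library (y axis, units of the deposited scale) by population (x axis), with circles for WT and triangles for Pep3 recipients and bars for the mean ± SD (n = 8). In the test, 13 of 15 interferon response genes rose from normal to tumour microglia, and all 16 homeostatic microglia genes were lower in each macrophage population than in tumour microglia.

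Differentiated macrophages against tumour microglia addressed how far these populations of tumour-bearing mice differ. Microglial identity genes were lower in the macrophages as a block, and genes of blood-derived macrophages were higher. P2ry12 fell by 2.43 ± 0.41, Tmem119 fell by 2.37 ± 0.30, Sall1 fell by 2.18 ± 0.40 and Cx3cr1 fell by 2.44 ± 0.29. Siglech, a microglial lectin, fell by 3.02 ± 0.40, and the fructose transporter Slc2a5 fell by 3.14 ± 0.47. For each of these 6 genes the libraries of the groups did not overlap, and the highest adjusted p was 0.00023. For any gene named by the size of its difference, lack of overlap was a condition and is no support. All 16 homeostatic microglia genes fell, also when adjusted over the list alone and with the library medians subtracted (camera adjusted p = 1.2e-23), and this call held with an estimated correlation (adjusted p = 0.030).

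On the other side, Acp5, tartrate-resistant acid phosphatase, rose by 5.48 ± 0.41 and the coagulation factor F7 by 4.96 ± 0.47. Fabp5, a fatty acid binding protein, rose by 4.85 ± 0.43, the matrix protein Tgfbi by 4.58 ± 0.33, and Runx3, a transcription factor, by 4.34 ± 0.61. Ccr2, the receptor of monocyte chemoattractants, rose by 3.26 ± 0.48, and the integrin Itga4, used to tell blood-derived macrophages from microglia, by 2.74 ± 0.50. Of 14 monocyte-derived macrophage genes, 14 rose, also when adjusted over the list alone, and 13 with the library medians subtracted (camera adjusted p = 1.1e-05, but adjusted p = 0.18 with an estimated correlation). Of 15 monocyte genes, 13 rose, 0 fell and 2 did not pass, with the same counts when adjusted over the list alone and 8 rising with the medians subtracted (camera adjusted p = 0.0037, but adjusted p = 0.30 with an estimated correlation).

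Of 13 alternative activation genes, 9 rose, 1 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.045, but adjusted p = 0.40 with an estimated correlation). The mannose receptor Mrc1 rose by 3.38 ± 0.52, the chitinase-like Chi3l3 by 3.56 ± 0.72 and the PD-1 ligand Pdcd1lg2 by 3.59 ± 0.54. Arg1 rose by 3.58 ± 0.87 (adjusted p = 0.0023), but was not called without differentiated macrophage library 28 (2.86), and its difference was -1.34 without all 9 libraries that kept under 50%. Of 11 MHC class II genes, 5 rose, 1 fell and 5 did not pass, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.59). H2-Eb1 rose by 1.93 ± 0.39 and H2-Ab1 by 1.79 ± 0.40, against a median of all genes of 0.65, and with the library medians subtracted H2-Ab1 had a difference of 1.12 (adjusted p = 0.029). Il1rn, the interleukin 1 receptor antagonist, rose by 2.90 ± 0.50 and Il1b by 2.61 ± 0.54, while Il1a fell by 2.57 ± 0.44. The inflammatory cytokine list holds Il1b and Il1a but not Il1rn. Of its 11 genes, 4 rose, 2 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.59).

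Several lists were lower relative to all genes. Of 16 lysosome genes, 5 fell, 1 rose and 10 did not pass, with the same counts when adjusted over the list alone, and 11 fell with the library medians subtracted (camera adjusted p = 0.00095, but adjusted p = 0.18 with an estimated correlation). Cd68, a lysosomal membrane glycoprotein, fell by 2.10 ± 0.53, but was not called without differentiated macrophage library 28 (-0.87). Of 15 macrophage and microglia transcription factors, 4 rose, 5 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.038, but adjusted p = 0.18 with an estimated correlation). Of 16 oxidative phosphorylation genes, 2 fell, 0 rose and 14 did not pass, and 0 passed when adjusted over the list alone by limma (camera adjusted p = 0.012, but adjusted p = 0.30 with an estimated correlation). Of 19 proliferation genes, 1 rose, 2 fell and 16 did not pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.014, but adjusted p = 0.37 with an estimated correlation). MHC class I (1 of 12 fell, 0 rose, 11 did not pass) and interferon response genes (1 of 15 fell, 0 rose, 14 did not pass) were called lower at a camera adjusted p of 0.038 each, with 0 members passing when adjusted over the list alone. For these lists the values were adjusted p = 0.36 and adjusted p = 0.42 with an estimated correlation. Of 16 immediate early genes, 2 fell, 0 rose and 14 did not pass, with the same counts when adjusted over the list alone. Their camera adjusted p was 0.038, and adjusted p = 0.42 with an estimated correlation.

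Markers of other cells were higher beside the macrophage lists. All 5 measured T cell markers rose, also when adjusted over the list alone (camera adjusted p = 0.014, but adjusted p = 0.30 with an estimated correlation). Of 7 glioma cell markers, 6 rose, 0 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.018, but adjusted p = 0.34 with an estimated correlation). Of 7 border macrophage genes, 4 rose, 1 fell and 2 did not pass, with 5 rising and 1 falling when adjusted over the list alone, and camera did not call the list (adjusted p = 0.20). Of 7 dendritic cell genes, 5 rose, 0 fell and 2 did not pass, with the same counts when adjusted over the list alone and no call by camera (adjusted p = 0.32). With the medians subtracted, 4 border macrophage genes rose and 1 fell, and 2 dendritic cell genes rose and 1 fell. By fry, which does not compare a list with other genes, both lists were higher (adjusted p = 4.0e-05 and 0.00013). Fry called 21 of the 32 lists higher in this comparison, so its calls are not particular to border macrophage or dendritic cell genes. Both lists share members with the alternative activation list, Mrc1 among those of border macrophages. The neuronal gene Stmn2 rose by 2.25 ± 0.33 and Col1a2, a collagen gene of fibroblasts and pericytes, by 2.08 ± 0.37.

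In all, 6510 genes were higher and 1116 lower in differentiated macrophages. The median difference of all genes was 0.652, and with the median of each library subtracted 3486 genes were higher and 3385 lower, among them 3486 and 1116 of the genes above. With the medians subtracted, 2 class II genes rose and 2 fell, 6 alternative activation genes rose and 1 fell, 3 cytokines rose and 4 fell, and 4 transcription factors rose and 7 fell. In the same setting 7 class I, 5 interferon, 8 oxidative phosphorylation, 4 proliferation and 5 immediate early genes fell and 0 rose, and 5 T cell and 6 glioma markers rose. By camera, 5 lists were higher and 8 lower, and with an estimated correlation 0 were higher and 1 lower. Camera by preset correlation and the list median differed in sign for immediate early genes, which were called, and for disease-associated microglia, inflammatory cytokine, immune checkpoint, glycolysis and oligodendrocyte genes, which were not. The counts were 4162 higher and 735 lower without tumour microglia library 27, and the lower count was 420 without differentiated macrophage library 28 and 709 without undifferentiated macrophage library 8. Without all 9 libraries that kept under 50%, limma called 0 genes with the terms for the removed directions (6 residual degrees of freedom, 1935 at an unadjusted p under 0.05), and without these terms 4620 higher and 836 lower, 4546 and 744 of them among the genes above. Fitted to only the libraries of the groups compared (3 residual degrees of freedom), limma called 48 higher and 7 lower, 47 and 3 of them among the genes above. It called 0 in WT (2332) or Pep3 recipients alone (1930).

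Undifferentiated macrophages against tumour microglia asked the same of the second macrophage population. Monocyte genes were among those with the largest differences. Ly6c2, a surface antigen of inflammatory monocytes, rose by 5.57 ± 0.44, the calcium-binding S100a6 by 5.35 ± 0.56, Ccr2 by 4.98 ± 0.50 and Tgfbi by 5.06 ± 0.35. Mefv, which encodes the inflammasome protein pyrin, rose by 5.36 ± 0.55, and Nr1h3, a sterol-sensing nuclear receptor, by 5.12 ± 0.57. The 8 libraries of each group did not overlap for any of these 6 genes, and the highest adjusted p was 4.4e-06. Again lack of overlap was a condition for genes named by the size of their difference, and is no support for those. All 15 monocyte genes rose, also when adjusted over the list alone, and 12 with the library medians subtracted (camera adjusted p = 2.0e-07, but adjusted p = 0.064 with an estimated correlation). All 14 monocyte-derived macrophage genes rose, also when adjusted over the list alone, and 12 with the medians subtracted (camera adjusted p = 1.4e-06, but adjusted p = 0.11 with an estimated correlation).

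Microglial genes were again lower as a block. The differences were -3.23 ± 0.43 for P2ry12, -2.87 ± 0.31 for Tmem119, -2.70 ± 0.30 for Cx3cr1, -2.64 ± 0.42 for Sall1 and -3.76 ± 0.41 for Siglech. All 16 homeostatic microglia genes fell, also when adjusted over the list alone and with the library medians subtracted (camera adjusted p = 1.0e-29), and this call held with an estimated correlation (adjusted p = 0.011). The chemokine Ccl4 fell by 5.72 ± 1.02 and Ccl12 fell by 2.55 ± 0.41. Of 13 chemokines, 1 rose, 4 fell and 8 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.084). Cst7 fell by 3.21 ± 0.43, in a disease-associated microglia list of 17 of which 6 rose, 5 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.028, but adjusted p = 0.28 with an estimated correlation). C1qb, a chain of complement C1q, fell by 2.54 ± 0.35, while Cfb and Cfp of the alternative complement pathway rose by 3.15 ± 0.46 and 3.79 ± 0.56. Of 11 complement genes, 3 rose, 5 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.017, but adjusted p = 0.11 with an estimated correlation).

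Il1b rose by 2.98 ± 0.57, Il1rn by 3.28 ± 0.52 and Mrc1 by 3.31 ± 0.54, and Arg1 by 3.35 ± 0.90 (adjusted p = 0.0054). Of 13 alternative activation genes, 8 rose, 1 fell and 4 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.11). H2-Ab1 rose by 1.61 ± 0.41, but with the library medians subtracted its difference was 0.89 (adjusted p = 0.097). Of 11 MHC class II genes, 5 rose, 1 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.00). Of 15 interferon response genes, 0 passed in limma, also when adjusted over the list alone (camera adjusted p = 0.11).

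Of 16 lysosome genes, 1 rose, 6 fell and 9 did not pass, and 2 rose and 7 fell when adjusted over the list alone (camera adjusted p = 2.0e-05, but adjusted p = 0.064 with an estimated correlation). Of 19 proliferation genes, 3 fell, 0 rose and 16 did not pass, and 0 passed when adjusted over the list alone, while 13 fell with the library medians subtracted (camera adjusted p = 2.2e-05, but adjusted p = 0.22 with an estimated correlation). Of 16 oxidative phosphorylation genes, 1 rose, 2 fell and 13 did not pass, and 1 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.25 with an estimated correlation). Of 15 macrophage and microglia transcription factors, 4 rose, 5 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.090 with an estimated correlation). Of 5 T cell markers, 4 rose, 0 fell and 1 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 0.032, but adjusted p = 0.28 with an estimated correlation). Of 7 glioma cell markers, 6 rose, 0 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.011, but adjusted p = 0.25 with an estimated correlation). Of 7 border macrophage genes, 5 rose, 1 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.33), and of 7 dendritic cell genes, 3 rose, 0 fell and 4 did not pass, with 5 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.36).

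In all, 6448 genes were higher and 913 lower in undifferentiated macrophages. The median difference of all genes was 0.715, and with the median of each library subtracted 2934 genes were higher and 2862 lower, among them 2934 and 913 of the genes above. With the medians subtracted, 1 class II gene rose and 2 fell, 5 alternative activation genes rose and 1 fell, 2 disease-associated microglia genes rose and 8 fell, 3 complement genes rose and 6 fell, 3 transcription factors rose and 7 fell, and 1 lysosome gene rose and 11 fell. In the same setting 4 chemokines, 4 interferon and 10 oxidative phosphorylation genes fell and 0 rose, and 4 T cell and 6 glioma markers rose. By camera, 4 lists were higher and 7 lower, and with an estimated correlation 0 were higher and 1 lower. The list median and the test differed in sign for both MHC classes, interferon response, inflammatory cytokine, chemokine, immune checkpoint, lipid efflux, glycolysis and immediate early genes, none of which was called. The higher count was 3722 without differentiated macrophage library 31. Without all 9 libraries that kept under 50%, limma called 3 genes higher and 0 lower with the terms for the removed directions (6 residual degrees of freedom, 2550 at an unadjusted p under 0.05), and without these terms 4646 higher and 677 lower, 4564 and 617 of them among the genes above. Fitted to only the libraries of the groups compared (3 residual degrees of freedom), limma called 9 higher and 0 lower (3083 at an unadjusted p under 0.05), and all 9 were among the genes above. It called 0 genes in WT (1820) or Pep3 recipients alone (2097).

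**Figure D4:**
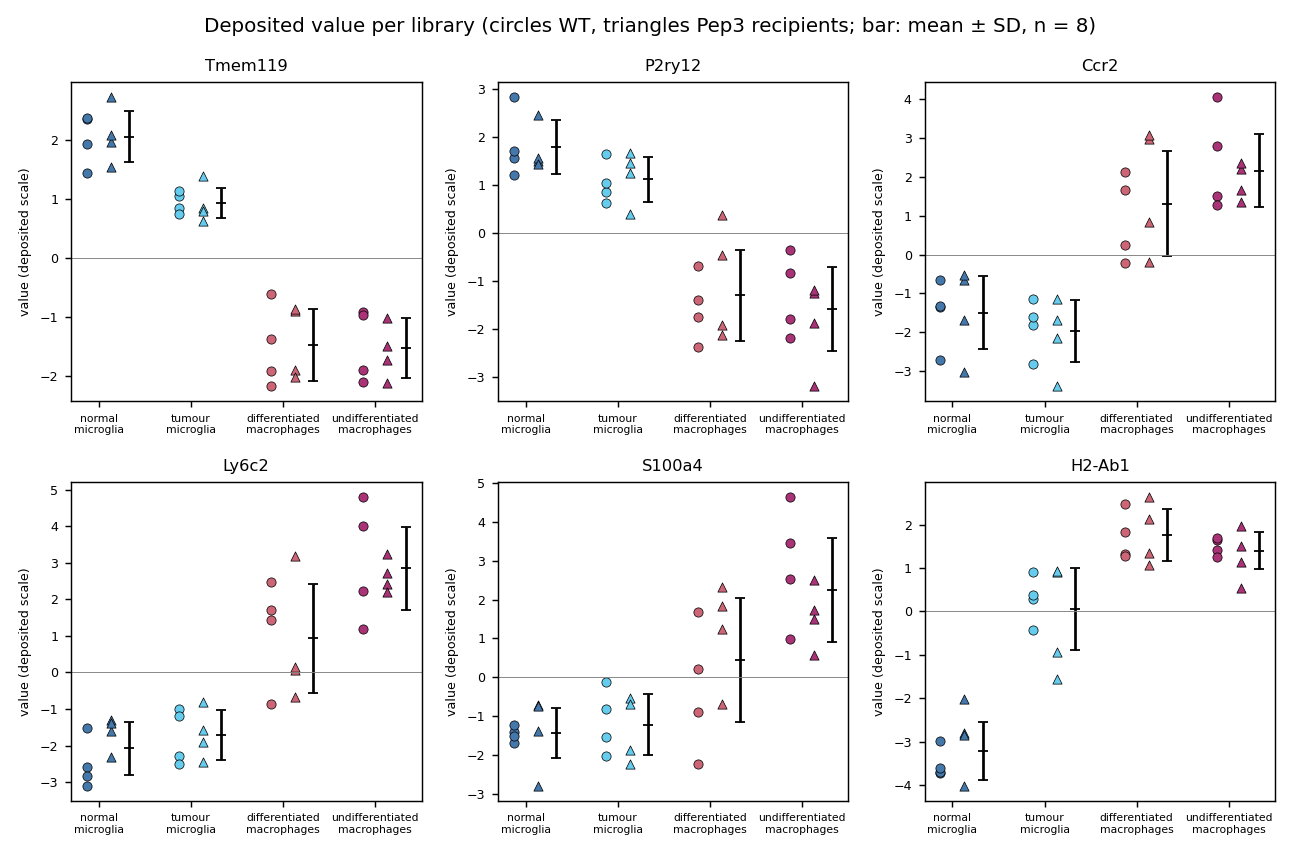
Score (y axis, units of the deposited scale) of Tmem119, P2ry12, Ccr2, Ly6c2, S100a4 and H2-Ab1 in each library by population (x axis), with circles for WT and triangles for Pep3 recipients and bars for the mean ± SD (n = 8). Mean Tmem119 was 2.06 in normal microglia, 0.93 in tumour microglia, -1.47 in differentiated and -1.52 in undifferentiated macrophages.

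Differentiated against undifferentiated macrophages addressed how the macrophage populations differ from each other. The monocyte list was called lower in differentiated macrophages, and 2 single genes passed the test. Chance cannot be excluded for the counts of genes or of lists. Ly6c2 was lower in differentiated macrophages by a difference of -3.17 ± 0.48 (adjusted p = 0.017), with a score of 0.93 ± 1.49 (SD, n = 8) against 2.85 ± 1.14 (SD, n = 8). S100a4, a calcium-binding protein abundant in monocytes, had a difference of -3.10 ± 0.51 (adjusted p = 0.032), with a score of 0.43 ± 1.60 (SD, n = 8) against 2.24 ± 1.34 (SD, n = 8). The libraries of the groups overlapped for both genes. These fitted differences are larger than those of the mean scores, because the fit holds terms for the removed directions. With no such terms the differences were -1.92 and -1.81, those of the mean scores, and neither gene was called. Of 15 monocyte genes, 2 fell, 0 rose and 13 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 1.1e-12), and this call held with an estimated correlation (adjusted p = 0.020) and with fry (0.023).

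Among other named marker genes, 6 did not pass here. Ccr2 had a difference of -1.72 ± 0.56, P2ry12 0.80 ± 0.47, Tmem119 0.50 ± 0.34, Arg1 0.23 ± 1.00, H2-Ab1 0.18 ± 0.46 and Itga4 0.04 ± 0.58, all with an adjusted p of 1.00. Camera called 4 lists higher in differentiated macrophages with 0 members passing in limma, also when adjusted over the list alone. These were the 16 homeostatic microglia genes (adjusted p = 2.8e-05, but adjusted p = 0.66 with an estimated correlation), the 17 disease-associated microglia genes (2.8e-05, but adjusted p = 0.12 with an estimated correlation), the 19 proliferation genes (0.0020, but adjusted p = 0.71 with an estimated correlation) and the 11 complement genes (0.035, but adjusted p = 0.27 with an estimated correlation).

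Over all genes, limma called 0 higher and 2 lower, and 491 had an unadjusted p under 0.05. These 491 are fewer than the 5% of 17586 genes that chance gives. Of 100 splits of the libraries, 5 with the real one included gave 2 genes or more, so chance cannot be excluded. Neither gene was called with a term for sets of 8 library numbers (Ly6c2 -3.11, S100a4 -2.97) or with no term for the removed directions (Ly6c2 -1.92, S100a4 -1.81), nor S100a4 with population means (-3.00) or quantile normalisation (-2.95). The list median and the test differed in sign for dendritic cell, inflammatory cytokine, chemokine, glycolysis, NK cell and astrocyte genes, none of which was called. Ly6c2 was not called without differentiated macrophage library 7 (-3.10), 23 (-3.14) or 4 (-2.69), or undifferentiated macrophage library 16 (-3.12), 13 (-3.03) or 21 (-3.02). S100a4 was not called without normal microglia library 2 (-3.26) or 9 (-3.09), differentiated macrophage library 7 (-3.11), 23 (-2.76), 31 (-3.10), 4 (-2.89) or 20 (-3.05), or undifferentiated macrophage library 16 (-3.19), 32 (-2.89), 13 (-3.05) or 21 (-2.94). The count of lower genes was therefore 0 without libraries 7, 23, 4, 16, 13 or 21 and 1 without libraries 2, 9, 31, 20 or 32. Within experiment 3, the WT recipients, limma called 0 genes (861 at an unadjusted p under 0.05), and within experiment 4, the Pep3 recipients, it called 1 lower, which was neither Ly6c2 nor S100a4. The difference of Ly6c2 was -4.21 within experiment 3 and -2.99 within experiment 4, and that of S100a4 -5.22 and -0.86, each with 3 residual degrees of freedom. Camera called 2 lists lower within experiment 3 and 0 within experiment 4, so the monocyte list was not called in the latter.

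The difference between recipient strains in a contrast could be tested for each comparison. For each macrophage population against tumour microglia it is also a difference between experiments 4 and 3, so strain and experiment cannot be told apart. For tumour against normal microglia the strain difference passed for 884 genes, 72 with a higher and 812 with a lower contrast in Pep3 recipients. Ier3, an immediate early gene, had a contrast 5.18 ± 1.26 higher in Pep3 than in WT recipients (adjusted p = 0.024). For Phyhipl the difference was -4.63 ± 1.00 (0.015) and for Stmn2 -4.44 ± 1.00 (0.018). In WT recipients the deposited means of Ier3, Phyhipl and Stmn2 differed by 1.07, -1.45 and -0.44. Fits to these recipients alone gave the opposite signs, -1.59, 0.43 and 1.35, so the strain differences of these genes may rest on the terms for the removed directions. For differentiated macrophages against tumour microglia 79 genes passed, a count that ran from 0 to 464 over the omissions of 1 library and stayed within 1.5 times only without undifferentiated macrophage library 21 (89). For undifferentiated macrophages against tumour microglia 1 gene passed, mKIAA0897, chosen after its values were seen, with a difference of 7.45 ± 1.15 (adjusted p = 0.021). That count was 0 without normal microglia library 2, 1 or 25, tumour microglia library 30, 11, 19 or 27, or undifferentiated macrophage library 8, 24 or 13. Between the macrophage populations limma called 0, with 710 at an unadjusted p under 0.05, and 1 without differentiated macrophage library 15. The 884 genes became 400 without normal microglia library 2, 213 without 1, 546, 562, 317, 283 and 236 without tumour microglia libraries 6, 3, 11, 19 and 27, 33 without differentiated macrophage library 31 and 51 without undifferentiated macrophage library 8. In microglia limma called 0 with no term for the removed directions (385 at an unadjusted p under 0.05) and 0 with a term for sets of 8 library numbers (3147), 31 with quantile normalisation and 51 with library weights. Both these 385 and the 710 between the macrophage populations were fewer than the 5% of 17586 genes that chance gives.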

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

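Of the tests in this part, that of the experiment number was chosen after the result was seen. The contrast of tumour against normal microglia differed between recipient strains for 884 genes, by limma's test of the difference itself, and 4 of 100 splits of the libraries, the real one included, gave as many, with 1275 in the highest other split. The count was 0 with a term for sets of 8 library numbers, 0 with no term for the removed directions (3147 and 385 at an unadjusted p under 0.05), 31 with quantile normalisation and 51 with library weights, so the splits alone do not settle it. The 385 are fewer than the 5% of 17586 genes that chance gives. Without normal microglia library 2, the Pep3 library of that population that kept most of its own variation, the count was 400, which is what an effect resting partly on 1 library needs, but it was 33 without differentiated macrophage library 31, so library 2 alone does not set it. Experiment cannot be told apart from strain, since each experiment held 1 strain of normal microglia. A biological difference between the strains or the chimera directions stays open as untested.

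Among named genes the strain difference passed for Ier3 (5.18), Phyhipl (-4.63) and Stmn2 (-4.44) in tumour against normal microglia. Fits to WT recipients alone gave these genes contrasts opposite in sign to the deposited means, so their strain differences may rest on the terms for the removed directions. For differentiated macrophages against tumour microglia 79 genes differed between strains, with none of the other splits as large (1 of 100 with the real one included, highest other 26), but limma called 0 with no term for the removed directions and 0 with the medians subtracted (346 and 2371 at an unadjusted p under 0.05). For undifferentiated macrophages against tumour microglia 1 gene did, with 4 of 100 splits as large, the real one included, and 1 in the highest other split, a rate near that of a single false call, so chance is not excluded.

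In 8 of 198 groups of 8 libraries tested, 1 library lay far from the others, where chance gives about 9.9 at 1 in 20. In tumour microglia these were Ccl8 in library 19 (-3.17, nearest other -1.20), Cd300lf in library 6 (-0.224, nearest 0.523), Chi3l3 in library 6 (-4.56, nearest -2.07) and Slc2a5 in library 3 (2.87, nearest 1.78). In normal microglia they were Mcm5 in library 9 (1.02, nearest -1.18) and Top2a in library 17 (-3.10, nearest -1.27). In macrophages they were Cd68 in undifferentiated library 32 (-3.23, nearest -0.985) and Fabp5 in differentiated library 23 (0.750, nearest 2.34).

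For each count 100 splits of the libraries were used, the real one included. For tumour against normal microglia, the real split alone, 1 of 100, gave 2936 genes or more, with 2493 in the highest other split, and 2 of 100 gave 17 lists or more, with 18 in the highest other. For differentiated macrophages against tumour microglia, the real split alone, 1 of 100, reached 7626 genes (highest other 5653) and again 1 of 100 reached 13 lists (highest other 11). For undifferentiated macrophages against tumour microglia, the real split alone, 1 of 100, reached 7361 genes (highest other 3537), and 2 of 100, the real one included, reached 11 lists (highest other 12). The other splits had larger error factors than the real one, with a median of 0.621 against 0.516 for tumour against normal microglia, 0.582 against 0.536 for differentiated and 0.571 against 0.560 for undifferentiated macrophages against tumour microglia, so they could call fewer genes. The real split alone reached the gene count in each of these comparisons, and the list count for differentiated macrophages against tumour microglia. Because the other splits could call fewer genes, this ranking by itself does not exclude chance for any of these counts. For differentiated against undifferentiated macrophages, 5 of 100 gave 2 genes or more (highest other 3) and 27 gave 5 lists or more (highest other 12), so chance cannot be excluded.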

How the results depend on the processing

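The settings without a term for the removed directions, with library medians subtracted, and without the 9 libraries that kept under 50% of their own variation were chosen after the data were seen, and where a value changed the cause was not tested unless given. A minimum difference of 1 unit left every gene count within 1.5 times. Of 126 named gene values, 124 kept their direction and call with the medians subtracted, 124 with quantile normalisation, 123 with no term for the removed directions, 124 with population means, 123 with the term for sets of 8 library numbers and 119 with library weights, but 12 in WT and 12 in Pep3 recipients alone and 14 without the 9 libraries, settings that left 3, 3 and 6 residual degrees of freedom. The number was 54 with only the groups compared, with 72 losing their call, and 109 without the 9 libraries and without the term. No sequencing depth was given, so what depth limits could not be assessed. Other pseudocounts, filters on low values, other count normalisations and count-based models were not run, since signed scores allow none of them, and contrasts of the recipient strains within a population could not be fitted.

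In tumour against normal microglia, 1038 genes were lower and 1 list was lower with population means, 208 genes were higher and 537 lower with library weights, and 1240 were lower with quantile normalisation. With no term for the removed directions 1235 genes were higher and 1 list was lower, and with the medians subtracted 1358 genes were higher and 1336 lower. With only the groups compared 214 genes were higher and 259 lower. Limma called 0 higher and 0 lower in WT recipients (1959 at an unadjusted p under 0.05; lists 5 higher, 1 lower), in Pep3 recipients (1895; lists 3 higher, 1 lower) and without the 9 libraries (1866; lists 7 higher, 2 lower). Without the 9 libraries and without the term, 109 genes were higher, 24 lower and 1 list lower. With an estimated correlation 8 lists were higher and 0 lower.

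In differentiated macrophages against tumour microglia, 3301 genes were higher and 3085 lower with quantile normalisation, and 3486 and 3385 with the medians subtracted. Fewer lists were lower with library weights (4), with only the groups compared (3) and without the 9 libraries and the term (4). With only the groups compared 48 genes were higher and 7 lower. Limma called 0 higher and 0 lower in WT recipients (2332 at an unadjusted p under 0.05; lists 3 higher, 1 lower), in Pep3 recipients (1930; 1 list lower) and without the 9 libraries (1935; lists 2 higher, 3 lower). With an estimated correlation 0 lists were higher and 1 lower, and with fry, which tests a list without comparing it with other genes, 21 were higher and 2 lower.

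In undifferentiated macrophages against tumour microglia, 2818 genes were higher, 2634 lower and 4 lists lower with quantile normalisation, and 2934 genes higher and 2862 lower with the medians subtracted. With only the groups compared 9 genes were higher, 0 lower (3083 at an unadjusted p under 0.05) and 4 lists lower. Limma called 0 higher and 0 lower in WT (1820; lists 2 higher, 1 lower) and in Pep3 recipients (2097; 2 lists lower), and 3 higher and 0 lower without the 9 libraries (2550; 2 lists lower). With an estimated correlation 0 lists were higher and 1 lower, and with fry 20 higher and 2 lower.

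In differentiated against undifferentiated macrophages, 1 gene was lower with population means, 1 with quantile normalisation, 4 with library weights (2 lists lower), 1 in Pep3 recipients (0 lists lower) and 1 without the 9 libraries (lists 2 higher, 2 lower). Limma called 0 lower with the term for sets of 8 library numbers (505 at an unadjusted p under 0.05), in WT recipients (861; lists 1 higher, 2 lower), with only the groups compared (680), with no term for the removed directions (353) and without the 9 libraries and the term (540). Each of these counts at an unadjusted p was below 5% of the 17586 genes. Where their calls were lost, Ly6c2 and S100a4 had differences of -3.47 and -3.74 with only the groups compared, -4.21 and -5.22 in WT and -2.99 and -0.86 in Pep3 recipients. Without the 9 libraries Ly6c2 lost its call (-3.77) and S100a4 kept it (-4.24). Without these libraries and the term both calls were lost (-2.85 and -2.66). With an estimated correlation and with fry 0 lists were higher.

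For the strain difference in microglia limma called 0 genes with the term for sets of 8 library numbers (3147 at an unadjusted p under 0.05), 0 with no term for the removed directions (385) and 0 without the 9 libraries (1462). It called 51 with library weights, 31 with quantile normalisation, 374 with the medians subtracted and 1 without the 9 libraries and the term.

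Leaving out each library in turn gave 89 to 935 higher and 82 to 2836 lower genes in tumour against normal microglia (lists 11 to 14 and 1 to 4), and 4162 to 6829 and 420 to 1194 in differentiated macrophages against tumour microglia (lists 4 to 5 and 4 to 10). The ranges were 3722 to 6731 and 647 to 960 in undifferentiated macrophages against tumour microglia (lists 3 to 5 and 5 to 9), 0 to 0 and 0 to 3 between the macrophages (lists 2 to 6 and 1 to 3), and 33 to 1179 for the strain difference in microglia.

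Values that reversed in tumour against normal microglia were Il1b -1.86, Mcm5 -1.18, Ldha -0.76, Ier3 -1.59, Phyhipl 0.43 and Stmn2 1.35 in WT recipients. In Pep3 recipients they were Cd74 -0.33, H2-Ab1 -0.60, H2-Eb1 -1.25, Tnf -0.16, Il1b -1.16, Cst7 -0.69 and Cd274 -0.12, and without the 9 libraries Il1b -0.31. Ube2c reversed in undifferentiated macrophages against tumour microglia in WT recipients (1.67), and Arg1 in differentiated macrophages against tumour microglia without the 9 libraries (-1.34). None of these reversed values passed the test. In all 7 cases in WT and all 7 in Pep3 recipients the means of the deposited values had the sign opposite to the fitted value, as for H2-Ab1 in Pep3 recipients (2.76), so the fitted sign comes from the terms for the removed directions.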

Other observations

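In this part the test of a uniform offset and the choice of Xist came after the result was seen. Single genes of matrix remodelling, hypoxia response and cholesterol synthesis were higher in macrophages than in tumour microglia, and camera called none of these 3 lists. Over all 17586 genes, 6510 rose in differentiated and 6448 in undifferentiated macrophages, and 3486 and 2934 with the library medians subtracted. The cholesterol synthesis counts are near or below these shares, as are the hypoxia response counts with the medians subtracted. In differentiated macrophages against tumour microglia 10 of 14 matrix remodelling genes rose, 1 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.16). Adam8, a membrane protease, rose by 3.71 ± 0.62 and Fn1, fibronectin, by 2.55 ± 0.56. In undifferentiated macrophages 9 rose, 3 fell and 2 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.39), and Mmp14, a membrane-bound collagenase, rose by 2.93 ± 0.42. With the library medians subtracted 6 rose and 3 fell in each. Of 10 hypoxia response genes 6 rose, 0 fell and 4 did not pass in differentiated macrophages, with the same counts when adjusted over the list alone (camera adjusted p = 0.59), and 5 rose, 0 fell and 5 did not pass in undifferentiated macrophages, with 6 rising when adjusted over the list alone (camera adjusted p = 0.38). With the medians subtracted 2 and 1 rose and 1 fell in each. Of 14 cholesterol synthesis genes 4 rose in differentiated and 6 in undifferentiated macrophages, 0 fell, and the counts were the same when adjusted over the list alone, with camera adjusted p of 0.67 and 0.44. With the medians subtracted 2 rose and 1 fell in differentiated and 1 rose in undifferentiated macrophages.

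Markers of non-myeloid cells were higher in macrophages than in tumour microglia as single genes, but camera called none of the following lists. In differentiated macrophages 3 of 3 NK cell, 4 of 5 B cell, 6 of 8 astrocyte, 5 of 6 neuron and 5 of 7 endothelial and pericyte markers rose, and 1 astrocyte marker fell. Adjusted over the list alone, 3, 4, 6, 5 and 6 rose. In undifferentiated macrophages 3 of 3, 4 of 5, 6 of 8, 5 of 6 and 4 of 7 rose, with 1 B cell and 1 astrocyte marker falling, and 3, 4, 6, 6 and 4 rose when adjusted over the list alone. With the library medians subtracted, 1 neuron and 1 endothelial marker rose in each macrophage population. Over all 17586 genes 6510 and 6448 rose, and 3486 and 2934 with the medians subtracted. Levels of these genes are not given by the scores, so a share of other cells cannot be computed.

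Most genes called between macrophages and tumour microglia were higher in macrophages (85.4% in differentiated and 87.6% in undifferentiated macrophages). With the library medians subtracted the shares were 50.7% and 50.6%, but this step centres the differences whatever their cause. A uniform offset between libraries may account for the excess of higher genes. Oxidative phosphorylation genes lay -0.93 from the median of all genes in differentiated macrophages (bootstrap SE 0.222), so not all genes moved alike, but a change of these genes themselves would give the same value, and the offset stays open. Better detection of low-level genes in macrophage libraries was tested by the relation of the difference to the residual SD across genes, which are not independent replicates, and Spearman's rho was 0.0332 in differentiated and 0.0495 in undifferentiated macrophages. A rho under 0.05 had been set beforehand as a value against it, but the residual SD stands in for a level that the table does not hold, so that bound cannot be relied on and this explanation stays open as well, as does a biological difference between the populations.

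Xist, the RNA of the inactive X chromosome, was chosen after its values were seen. It was lower in macrophages than in tumour microglia, with a difference of -1.30 ± 0.34 in differentiated (adjusted p = 0.0041) and -1.64 ± 0.36 in undifferentiated macrophages (adjusted p = 0.0011). Its scores ran from -1.12 to -0.28 in differentiated and from -1.34 to -0.39 in undifferentiated macrophages, against -0.87 to 1.94 in tumour microglia. Grafted cells of another sex than the recipient may give such a difference, but 0 of the Y-linked genes chosen for the test were available, so it stays open and Y-linked genes were not analysed here. The sex of donors and recipients was not given in the sources used here.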
